A study of Mus musculus with 16 samples.

How the data were processed

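RNA was measured in whole cerebellum and whole lung of C57BL/6J mice at postnatal day 7 after treatment with dexamethasone or vehicle, with 4 arrays in each of the 4 groups. Dexamethasone is a synthetic glucocorticoid that acts on the glucocorticoid receptor. The dose and the schedule of treatment are not given in the sources used here. Total RNA was turned into biotin-labelled cRNA and hybridised to Affymetrix mouse arrays, per the labels' protocols.

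The deposited values are on a log2 scale and were made with RMA, per the submitters' processing notes, which name no version. The settings of background correction, normalization and summary are not given in the sources used here. RMA gives a value to every probe set whether or not its transcript is detected, and it compresses differences between dim probe sets, so folds of genes near the floor understate a change. Values ran from 3.15 to 14.8, and array medians from 5.87 to 6.00. Arrays give no read depth, and their number, 4 per group, limits the precision.

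Of 45101 probe sets, 64 were controls of the array. Among the others, 34945 were listed with 1 gene symbol, 932 with several, and 9160 with no gene in the table used here. Symbols were updated through the gene identifier, and 18032 of the 18193 genes took theirs from the RefSeq table. A gene was represented by the probe set with the highest mean over the 16 arrays, and 9010 genes had more than 1. No gene was named from a probe set with several symbols, and members of the fixed lists that no such probe set named are not analysed here. No filter on dim genes was applied, except as an alternative.

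Each gene was fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups and a variance moderated by eBayes. The 4 groups share a single estimate of the spread per gene, with 12 residual degrees of freedom. Contrasts were dexamethasone minus vehicle in cerebellum, the same in lung, the lung effect minus the cerebellum effect, and lung minus cerebellum in vehicle mice. P-values were adjusted by the Benjamini-Hochberg method over 18193 genes, and genes with an adjusted p under 0.05 were called. Errors beside a log2 change are the moderated standard errors of that fit, and values per group are given as mean ± SD.

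The fit was tested on simulated data with the means of the real groups and 200 changed genes among 18193. With a single spread per gene, a change of 2-fold was recovered for 90.5% of the changed genes in cerebellum and 93.5% in lung, and 2.69% and 4.10% of the calls were false. At 1.5-fold, 52.0% were recovered in cerebellum and 44.5% in lung. When each group instead kept the spread measured on its own 4 arrays, 14.4% of the calls in cerebellum and 29.8% in lung were false at 2-fold. Where a gene truly varies more in the groups compared than elsewhere, the pooled spread is too small. An SD of 4 arrays is itself imprecise, so the simulation cannot tell how often this holds in the real data. A fit on the arrays of a single tissue was among the alternatives.

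The main design, 32 gene lists and the rule for the genes named in the text were fixed before the data were examined. The rule took, for each dexamethasone comparison, the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between the groups of 4. It also took a fixed set of glucocorticoid, hedgehog and proliferation genes whatever their result, with 3 surfactant and matrix genes for lung. For each list described it took up to 4 called members with the smallest adjusted p, or the 2 brightest where none was called. For the difference between tissues and for the comparison of tissues it took the 6 largest each way, and for genes shared by both tissues the 6 that rose and the 6 that fell with the largest smaller fold. Each list was tested against the other genes with limma's camera at its preset correlation between genes of 0.01, adjusted over the 27 lists of cerebellum, the 24 of lung or the 19 tested in both. The same test with a correlation estimated from the data is given beside it. Another 5 lists were added after the data were seen and adjusted among themselves.

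Alternatives were the mean of a gene's probe sets, each probe set on its own, a filter on dim genes, quantile or cyclic loess normalization applied again, only the arrays compared, a variance trend with robust estimation, array weights, the level of Xist as a covariate, and leaving out each array in turn. Xist, which is transcribed from the inactive X chromosome of females, was used because sex is not given in the sources used here. Covariates for brainstem and erythroid markers, an exact permutation test of list levels, splits of the cerebellar arrays for the overlap and the leaving out of arrays for the overlap and for further named genes were added after the data were seen. All arrays share a hybridization date in the labels, so no batch could be tested.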

Results

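The study compared dexamethasone with vehicle in 2 organs of neonatal mice, whole cerebellum and whole lung. Each of the 4 groups held 4 arrays, 16 in all, from mice at postnatal day 7. Within a tissue, arrays correlated at 0.950 to 0.994, and between tissues at 0.804 to 0.864. No pair of arrays was identical. The median SD of a gene within a group ran from 0.148 in vehicle lung to 0.188 in dexamethasone lung on the log2 scale. Treatment separated the lung arrays on the first principal component, which held 59.6% of their variance. In cerebellum the first component, at 32.4%, had the dexamethasone array B39 and the vehicle array B79 at its ends. On the second, at 23.0%, the other 3 dexamethasone arrays lay at -36.25 to -18.66 and the vehicle arrays at 8.62 to 27.33, with B39 among the latter at 17.60. Array B46 of the dexamethasone lungs had the lowest mean correlation with its own group, at 0.981, and the lowest array weight, at 0.264. Xist was above 9 in 2 of 4 dexamethasone and 1 of 4 vehicle cerebella, and in 3 of 4 dexamethasone and 1 of 4 vehicle lungs, so the mix of sexes was unequal. No replicate number is shared between groups, and litter is not given in the sources used here, so p-values measure the spread between these samples and litter was not tested. The numbers also lie in separate ranges. In cerebellum vehicle arrays run from B78 to B81 and dexamethasone arrays from B39 to B52, and in lung from B12 to B22 and from B28 to B46. If the numbers follow litter or order of collection, these cannot be told apart from treatment. The 3′ minus 5′ log2 signal of the Gapdh control, a sign of RNA integrity, was 0.446 to 0.708 in dexamethasone and 0.84 to 1.04 in vehicle lungs, without overlap, and that of actin 0.451 to 0.642 and 0.611 to 0.667. In cerebellum both were highest in the vehicle array B81, at 0.518 and 0.942. In lung an effect of RNA integrity as read by Gapdh cannot be told apart from treatment, and no alternative adjusted for it.

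The vehicle groups show how far the organs differ without treatment. Scgb1a1, a secretory protein of airway club cells, was 998-fold higher in lung (log2 difference 9.96 ± 0.12). Scgb3a2, the surfactant proteins Sftpc and Sftpa1, the alveolar type 1 receptor Ager and the matrix protein Dpt were 623-fold, 550-fold, 489-fold, 369-fold and 325-fold higher there. In lung Scgb1a1 and Sftpc, at 14.37 and 14.63, lay near the highest value of any probe set, 14.83, so saturation can make their folds too small. Zic1, a transcription factor of granule neurons, was 598-fold higher in cerebellum. The Purkinje cell calcium-binding protein Calb1, the neuronal filament proteins Ina and Nefl, the tubulin-binding protein Stmn3 and the motor protein Kif5c were 329-fold, 315-fold, 261-fold, 291-fold and 241-fold higher in cerebellum. In all, 5086 genes were higher in lung and 5411 higher in cerebellum.

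In cerebellum, dexamethasone raised Fam107a, a glucocorticoid-responsive gene, 10.9-fold, from 7.49 ± 0.67 to 10.94 ± 0.32 (SD, n = 4; log2 change 3.45 ± 0.58, limma adjusted p = 0.00242). The muscle-type myosin-binding protein Mybpc1 rose 4.88-fold. Ptchd4, Itih3, the myelin proteins Mal and Mobp, the glutathione-degrading enzyme Chac1 and the GABA-A receptor subunit Gabra2 rose 2.73-fold to 3.17-fold. Of the probe sets of Ptchd4 1 of 2 was called, and 3 of 5 for Gabra2 and for Mobp. Mid1, an X-linked ubiquitin ligase, fell 9.24-fold (log2 change -3.21 ± 0.54), although only 1 of its 3 probe sets moved, and the log2 change was -3.82 without B80. The others had mean levels of 4.483 and 4.679, against 7.508, near the floor where a fall could hardly be seen. Scube2, the apelin receptor Aplnr, the thioredoxin-binding protein Txnip and 8430419K02Rik fell by 1.96, 1.76, 1.67 and 1.55 on the log2 scale, and Clec14a, Cd68 and Tek fell by 1.41, 1.27 and 1.25. For 8430419K02Rik and for Clec14a 1 of 2 probe sets was called. The call for Mobp was lost without B39, B50, B52, B79 or B80 (adjusted p 0.05 to 0.110), and that for Mal without B50, B79 or B80 (0.0535 to 0.0625). Fitted on the cerebellar arrays alone, both were lost (0.0926 and 0.0954), and Mobp also with the level of Xist as a covariate (0.0522). Cd68 was no longer called without B39, B50, B52, B79 or B80 (0.0577 to 0.0915).

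Some genes of the vessel wall and of collagen matrix fell in the treated cerebellum. Of 14 endothelial genes, 7 fell and 1 rose, with a median log2 change of -0.59 (camera adjusted p = 1.4e-10, against adjusted p = 0.102 with an estimated correlation). Adjusted over the list alone, 10 fell and 1 rose. The angiopoietin receptor Tek and the junction proteins Cdh5, Esam and Cldn5 fell 2.38-fold, 2.16-fold, 1.58-fold and 1.85-fold. Of 12 genes in the fibrillar collagen list, which also holds collagen VI and associated proteins, 4 fell. Col5a2, Col1a1, Col3a1 and Col6a1 fell 1.87-fold, 2.23-fold, 1.99-fold and 1.47-fold. Adjusted over the list alone, 6 fell and 1 rose. The camera adjusted p was 5.42e-05, and adjusted p = 0.405 with an estimated correlation. An exact permutation test of the mean level gave p = 0.0286 (adjusted 0.11) for the endothelial and for the collagen list. Of 15 macrophage and microglial genes 2 fell, Tyrobp by 0.86 and Cd68 by 1.27, and 2 fell adjusted over the list alone (camera adjusted p = 0.00015, and adjusted p = 0.489 with an estimated correlation). Of 11 neutrophil genes 2 fell, S100a8 and S100a9, by 1.72 and 1.59, and 5 fell adjusted over the list alone (camera adjusted p = 0.000713, and adjusted p = 0.405 with an estimated correlation). Of 14 genes of the insulin-like growth factor axis, 1 fell, Igfbp4, by 0.83, and 2 adjusted over the list alone (camera adjusted p = 0.0167, and adjusted p = 0.153 with an estimated correlation). With dim genes left out that list was not called (adjusted p = 0.0631). The meninges list (adjusted p = 0.139) was called without B80 (adjusted p = 0.00338) and with the level of brainstem markers as a covariate (adjusted p = 0.035). The call for S100a9 was lost without B49, B50, B52, B78 or B79 (adjusted p 0.0871 to 0.127), that for S100a8 without the same arrays (0.0949 to 0.115), and that for Col6a1 without B39, B49, B52, B79 or B81 (0.0567 to 0.108). On the cerebellar arrays alone S100a8 and S100a9 were lost (both 0.13) and so was Col6a1 (0.0516). S100a8 and S100a9 were also lost with a variance trend (0.0629 and 0.0644) and with the level of Xist as a covariate (0.0516 and 0.0619). Without B39, S100a8 fell by 2.31. That for Cd68 was lost without B39, B50, B52, B79 or B80 (0.0577 to 0.0915).

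Of 18 oligodendrocyte and myelin genes, 4 rose and the median log2 change was 0.36. They were Gpr17, a receptor of oligodendrocyte precursors, at 1.88-fold, and the myelin proteins Mag, Mobp and Cnp at 1.76-fold, 2.73-fold and 1.36-fold. Adjusted over the list alone 7 rose (camera adjusted p = 0.001, and adjusted p = 0.489 with an estimated correlation). Without B79 the median was 0.21 and the adjusted p 0.0477. The call for Mag was lost without B39, B50, B52, B79 or B80 (adjusted p 0.0644 to 0.0962), and that for Cnp without any array but B78 (0.0601 to 0.125). On the cerebellar arrays alone both were lost (0.0678 and 0.109), and Cnp also with probe sets averaged (0.057) and with Xist as a covariate (0.0663). Of 15 genes of cholesterol synthesis 1 rose, the sterol oxidase Msmo1 at 1.61-fold, and 1 adjusted over the list alone (camera adjusted p = 0.00257, and adjusted p = 0.607 with an estimated correlation). Without the vehicle array B81, which had the highest level of the 18S ribosomal RNA control in its group, at 9.51 against 6.17 to 7.37, that list was no longer called (adjusted p = 0.0632), nor was Msmo1 (0.05), which was also lost when its probe sets were averaged (0.471). Single members of other neural lists rose: the granule neuron GABA-A receptor subunit Gabra6 (2.35-fold), the interneuron calcium-binding protein Pvalb (2.05-fold), Gng13 of Purkinje cells (1.63-fold) and the astrocytic aldolase Aldoc (1.63-fold). None of those 4 lists was called. Gng13 was lost without B49, B52 or any single vehicle array (adjusted p 0.0662 to 0.122), after quantile normalization (0.0687), with Xist as a covariate (0.08) and with probe sets averaged (0.0967). On the cerebellar arrays alone Gng13 (0.0799), Pvalb (0.0548) and Aldoc (0.0588) were lost, and Aldoc also with probe sets averaged (0.0693).

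Genes that glucocorticoids induce in many tissues were mostly not called in cerebellum. Of 25, Fam107a and Bcl6 (1.61-fold) rose, 5 rose adjusted over the list alone, and the list was not called (camera adjusted p = 0.127). Without B81 it was called (adjusted p = 0.0114). Bcl6 was no longer called without B39, B50, B52, B78, B79 or B80 (adjusted p 0.0534 to 0.115), on the cerebellar arrays alone (0.0954) or with Xist as a covariate (0.053). With probe sets averaged the log2 change of Bcl6 was 0.35 in place of 0.69 (adjusted p = 0.0902). The chaperone Fkbp5 had a log2 change of -0.01 ± 0.27, Tsc22d3 0.14 ± 0.29, the kinase Sgk1 0.03 ± 0.14 and the clock gene Per1 0.07 ± 0.29. The glucocorticoid receptor Nr3c1 had -0.10 ± 0.10, and Hsd11b2, which inactivates endogenous glucocorticoids, -0.41 ± 0.19 (adjusted p = 0.285). Among the receptors and enzymes of steroid metabolism, the efflux transporter Abcb1a fell 1.65-fold, the only 1 of 11 called; adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.305).

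Sonic hedgehog signalling drives proliferation of granule neuron progenitors at this age. Of 15 hedgehog pathway genes, 1 fell, Gli3, 1.46-fold, and 1 adjusted over the list alone (camera adjusted p = 0.55). Gli3 was lost without any array but B52 (adjusted p 0.0685 to 0.107), with Xist as a covariate (0.0619) and with its probe sets averaged (0.348), where the log2 change was -0.25 in place of -0.54. Its target genes Gli1, Ptch1 and Mycn had log2 changes of 0.09 ± 0.21, 0.24 ± 0.12 and -0.03 ± 0.27, and Ccnd1 -0.12 ± 0.13, none of them called. The proliferation marker Mki67 had -0.64 ± 0.22 (adjusted p = 0.114). None of 29 cell cycle genes was called, over all genes or adjusted over the list alone, and Pcna and Mcm7 had -0.12 ± 0.10 and -0.27 ± 0.12. As a list they lay lower than other genes, with a median of -0.26 (camera adjusted p = 0.000104, and adjusted p = 0.607 with an estimated correlation). Without B39 the median was -0.13 and the adjusted p 0.0392. The granule neuron progenitor list had 0 of 11 genes called and a camera adjusted p of 0.674.

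In all, 516 genes were higher and 358 lower in the treated cerebellum, 4.80% of those tested, and 70 of the 874 differed at least 2-fold. The count fell to 528 without B50 and 557 without B79. Of 27 lists, 2 were called higher and 6 lower at the preset correlation and 0 with an estimated correlation, and the other 19 had adjusted p from 0.127 to 0.942. In exact permutation tests of the mean level, 0 of the 27 passed after adjustment. The smallest p this number of arrays can give is 0.0286, and 7 lists reached it, without overlap between the groups (adjusted 0.11). At that limit no list can pass over 27 unless many reach it together, so the count of 0 decides nothing.

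In lung, dexamethasone raised the neutrophil chemokine Cxcl2 25.6-fold, from 4.26 ± 0.22 to 8.94 ± 2.69 (SD, n = 4; log2 change 4.68 ± 0.83, limma adjusted p = 0.000365), with treated arrays from 5.66 in B31 to 11.54 in B46. That error is pooled with the cerebellar groups, where the SD of Cxcl2 was 0.09 and 0.12. The error and the adjusted p are thus too small for lungs that vary this much. The log2 change of Cxcl2 was 5.77 without B31, 4.09 without B40 and 3.81 without B46. The macrophage chitinase-like protein Chil3 rose 25.5-fold, the acute phase protease inhibitor Serpina3n 19.6-fold (11.2-fold without B46), the airway protein Bpifa1 19-fold and the methyltransferase Inmt 17.5-fold. Ms4a4d, the neutrophil collagenase Mmp8 and the neutrophil surface protein Cd177 rose 14.6-fold, 14.3-fold and 12.8-fold. The mitotic proteins Cenpf, Cep55 and Aspm fell 15.4-fold, 11.3-fold and 10.6-fold. Dcx, known as a microtubule protein of young neurons, fell 14.1-fold, with 2 of its 4 probe sets called. The class II antigen-presenting chain H2-Aa fell 13.3-fold, the growth factor Mdk 12.6-fold, Prss35 11.2-fold and Plcxd3 10.7-fold.

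**Figure D1:**
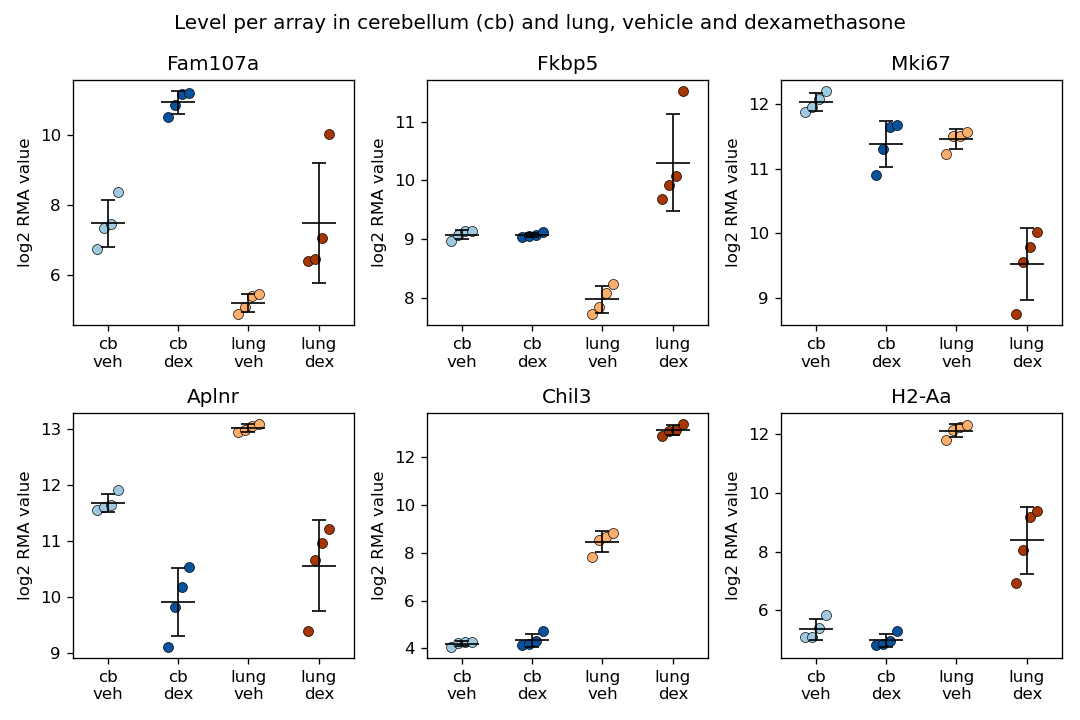
Level of 6 named genes on each array (log2 RMA value, vertical axis) in the 4 groups (horizontal axis), with points for the 4 arrays of a group, sorted by level, and the mean and SD as bars. Fam107a was higher after dexamethasone in both tissues, Aplnr lower in both, and Fkbp5, Chil3 and H2-Aa moved in lung, with log2 changes of 2.33, 4.67 and -3.74.

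Of 25 glucocorticoid-induced genes, 19 rose in lung, with a median log2 change of 1.27, and 20 adjusted over the list alone (camera adjusted p = 1.12e-08, and adjusted p = 0.208 with an estimated correlation). Fkbp5 rose 5.03-fold, the metallothionein Mt2 4.75-fold, the transcription factor Cebpd 3.47-fold, Per1 2.41-fold and the kinase inhibitor Errfi1 2.39-fold. Tsc22d3 had a log2 change of 0.72 ± 0.29 (adjusted p = 0.0719), with 1 of its 4 probe sets higher, and it passed without B31 (adjusted p = 0.0297). Sgk1 had 0.20 ± 0.14. Among 11 genes of steroid reception and metabolism 2 rose and 4 fell, and 3 and 4 adjusted over the list alone, with a median of 0.08 where camera gave the direction as lower (adjusted p = 0.973). Hsd11b1, which regenerates active glucocorticoid, rose 2.54-fold, while Hsd11b2 fell 2.03-fold and Nr3c1 1.32-fold. The efflux transporter Abcb1b rose 1.63-fold. The call for Nr3c1 was lost when its 6 probe sets were averaged (adjusted p = 0.134).

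Proliferation genes were lower in the treated lung. Of 29 cell cycle genes, 28 fell, with a median log2 change of -1.92, and 29 adjusted over the list alone (camera adjusted p = 7.48e-26, and adjusted p = 0.0801 with an estimated correlation). The mitotic checkpoint kinase Bub1 fell 8.66-fold, the topoisomerase Top2a 7.77-fold, Cdc20 5.63-fold, the kinase Cdk1 5.24-fold and Mki67 3.77-fold. Of 15 hedgehog pathway genes 8 fell and 1 rose, and 11 and 1 adjusted over the list alone (camera adjusted p = 0.000593, and adjusted p = 0.227 with an estimated correlation). The transcription factors Gli2 and Gli3 fell 2.83-fold and 2.46-fold and Ccnd2 1.79-fold, and the Wnt antagonist Sfrp1 rose 3.11-fold. Ccnd1 fell 1.51-fold and Ptch1 1.29-fold, and the call for Ptch1 was lost without B46, B12, B14 or B22 (adjusted p 0.0638 to 0.0695) on the lung arrays alone (0.104) and with the level of Xist as a covariate (0.0518). Gli1 had -0.57 ± 0.21 (adjusted p = 0.0512), called without B40 (0.0428), on the lung arrays alone (0.0183), with probe sets averaged (0.0499) and with a variance trend (0.0486). Mycn had -0.69 ± 0.26 (adjusted p = 0.0597), called without B28 or B31 (0.0463 and 0.0321), and its other 2 probe sets had 0.07 and 0.33.

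Epithelial lists lay higher at the preset correlation. Of 14 genes of alveolar type 2 cells and surfactant, 10 rose, as many adjusted over the list alone (camera adjusted p = 0.000593, and adjusted p = 0.142 with an estimated correlation). Sftpd rose 2.03-fold, Cebpa 1.74-fold, Cd36 1.67-fold, Sftpa1 1.63-fold and Sftpb 1.60-fold, while Sftpc, at 14.63 ± 0.04 in vehicle lung, had a log2 change of 0.04 ± 0.16. Its level lay near the highest value of any probe set, 14.83, where the signal can saturate, so a change of Sftpc could not be resolved. Of 12 alveolar type 1 genes 7 rose, 9 adjusted over the list alone, among them the water channel Aqp5 (2.21-fold), Hopx (1.70-fold), Clic5 (1.5-fold) and Emp2 (1.48-fold), with camera adjusted p = 0.000593, and adjusted p = 0.0801 with an estimated correlation. Of 11 airway genes 7 rose, as many adjusted over the list alone (camera adjusted p = 0.000903, and adjusted p = 0.142 with an estimated correlation), such as Scgb3a1 (5.73-fold), Cyp2f2 and Aldh1a7 (both 1.85-fold) and the ciliary dynein Dnah5 (1.59-fold).

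Lists of mesenchyme, matrix and vessels lay lower at the preset correlation. Of 16 genes of lung mesenchyme and elastic matrix 11 fell and 1 rose, as many adjusted over the list alone (camera adjusted p = 8.24e-06, and adjusted p = 0.142 with an estimated correlation). Tenascin C, Tnc, fell 9.03-fold, Ltbp2 4.71-fold and fibrillin Fbn2 4.39-fold, the crosslinking enzyme Lox rose 2.12-fold, and elastin, Eln, had 0.16 ± 0.08 (adjusted p = 0.154). Of 12 collagen genes 8 fell and 1 rose, as many adjusted over the list alone, with Col1a1, Col1a2 and Col5a2 down 3.08-fold, 2.73-fold and 1.90-fold and the prolyl hydroxylase subunit P4ha2 up 2.81-fold (camera adjusted p = 0.000593, and adjusted p = 0.227 with an estimated correlation). Of 14 endothelial genes 6 fell, 8 adjusted over the list alone (camera adjusted p = 0.000593, and adjusted p = 0.208 with an estimated correlation), with Aplnr, Emcn, Tie1 and Kdr down 5.47-fold, 2.09-fold, 1.94-fold and 1.89-fold. B46 lay apart from the other 3 treated lungs in the mean level of the hedgehog, collagen and endothelial lists, at 8.84, 10.90 and 10.06. Without it the collagen median was -0.49, against -0.76 with it.

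Lists of myeloid cells and of inflammation lay higher and the lymphocyte list lower at the preset correlation. All 11 neutrophil genes rose, over all genes and adjusted over the list alone, with a median log2 change of 2.09 (camera adjusted p = 1.12e-08, and adjusted p = 0.0544 with an estimated correlation). Mmp8 rose 14.3-fold, and the granule proteins Ltf, Ngp and Camp 6.78-fold, 5.91-fold and 5.42-fold. Of 15 macrophage genes 7 rose and 2 fell, as many adjusted over the list alone (camera adjusted p = 0.00432, and adjusted p = 0.327 with an estimated correlation), with Marco up 9.12-fold, Itgam 4.66-fold and Tyrobp 2.29-fold and Aif1 down 1.69-fold. Without B46 the median of that list was 0.25, against 0.64 with it. Of 17 inflammatory mediators 12 rose and 1 fell, as many adjusted over the list alone (camera adjusted p = 0.000593, and adjusted p = 0.208 with an estimated correlation), with Il1b up 5.96-fold, Icam1 2.21-fold and Vcam1 down 1.83-fold. Of 11 interferon response genes 7 rose, as many adjusted over the list alone (camera adjusted p = 0.00475, and adjusted p = 0.227 with an estimated correlation), among them Ifit1 (2.68-fold), Ifit3 (2.62-fold), Usp18 (1.69-fold) and Irf7 (1.48-fold). Of 15 T and B cell genes 7 fell, as many adjusted over the list alone (camera adjusted p = 0.000105, and adjusted p = 0.0544 with an estimated correlation), with the B cell protein Ms4a1 down 5.50-fold, the T cell receptor chain Cd3d 3.81-fold, Ighm 2.71-fold and Cd79a 1.97-fold.

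Markers of blood and heart tissue, which a lung dissection can hold, also differed. Of 8 erythroid genes 5 rose, 6 adjusted over the list alone, among them Rhag (3.25-fold), Ermap (2.70-fold), Klf1 (2.34-fold) and Tspan33 (2.18-fold), with camera adjusted p = 0.00261, and adjusted p = 0.227 with an estimated correlation. With dim genes left out it was not called (adjusted p = 0.062), and an exact permutation test of its mean level gave p = 0.0571 (adjusted 0.0722). With the erythroid level as a covariate the interferon, heart muscle and fatty acid lists were not called (adjusted p = 0.353, 0.118 and 0.0789). Their medians were 0.25, 0.52 and 0.23 with it, against 0.45, 0.78 and 0.17 without. Of 12 heart muscle genes 9 rose and 1 fell, and 9 and 2 adjusted over the list alone (camera adjusted p = 0.00953, and adjusted p = 0.227 with an estimated correlation), with Tnnt2 up 3.98-fold, Myh7 2.48-fold, Sln 2.06-fold and myoglobin, Mb, down 3.43-fold. Of 11 genes of fatty acid synthesis 5 rose, as many adjusted over the list alone, among them Scd1 (1.60-fold), Acaca (1.5-fold), Fasn (1.48-fold) and Acss2 (1.36-fold), with camera adjusted p = 0.0467, and adjusted p = 0.227 with an estimated correlation. That list was no longer called without B31, B40 or B19 (adjusted p 0.0503 to 0.0846), nor on the lung arrays alone (0.0603) or with probe sets averaged (0.0586), and its median of 0.17 was 0.11 without B19. Acaca was lost with its probe sets averaged (0.0909).

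In all, 2860 genes were higher and 2819 lower in the treated lung, 31.2% of those tested, and 1234 differed at least 2-fold. The Gapdh sign of RNA integrity differed between these groups without overlap, so its part in these calls is not known. Of 24 lists, 11 were called higher and 6 lower at the preset correlation and 0 with an estimated correlation. The other 7 had adjusted p from 0.0565 to 0.973. In exact permutation tests of the mean level, which do not compare a list with other genes, 18 of the 24 passed (adjusted p = 0.0381), among them the clock and apoptosis lists, which camera did not call, and not the erythroid list. Of the 7 lists not called in the main fit, camera called cholesterol synthesis without B46 or B22 (adjusted p = 0.000866 and 0.0459). It also did so with dim genes left out (0.0457), after quantile normalization (0.0286) and with the level of Xist as a covariate (0.0172). Immediate early genes were called without B31, B46 or B22 (0.0307, 0.018 and 0.032), with dim genes left out (0.0457), with a variance trend (0.0487) and with Xist (0.0172).

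The design has the same treatment in both organs, so the difference of the effects was tested itself. Chil3, Inmt, Bpifa1, Cxcl2, the metabolic kinase Pdk4 and the chemokine Ccl3 had the largest positive differences, the lung effect minus the cerebellar one, with interaction log2 values of 4.53 ± 0.26, 4.29 ± 0.18, 4.25 ± 0.41, 4.68 ± 1.17, 3.92 ± 0.73 and 3.88 ± 1.19. The cerebellar log2 changes of Pdk4, Ccl3 and Inmt were -1.01, -0.38 and -0.17, none of them called, and are part of these values. In cerebellum Cxcl2, Chil3 and Bpifa1 had vehicle means of 4.079, 4.198 and 4.116 and treated means of 4.075, 4.338 and 4.117. These lie near the floor, so their interaction values are little more than the lung change. Without B46 the interaction values of Cxcl2, Pdk4 and Ccl3 were 3.81, 3.16 and 2.80, and without B31 those of Cxcl2 and Ccl3 were 5.77 and 4.98. The call for Ccl3 was lost without B80 or B40 (adjusted p = 0.051 and 0.0536) and with a variance trend (0.0547). Dcx, Aspm, Cenpf, Shisa3, H2-Ab1 and Cep55 had the largest negative values, from -3.70 ± 0.22 to -3.46 ± 0.37. Shisa3 had cerebellar means of 4.145 in vehicle and 4.514 in treated mice, near the floor, where a fall could hardly be seen. Those of H2-Ab1 were also low, at 5.828 and 6.026, against 10.105 in vehicle lung. Glucocorticoid-induced genes differed, with 12 of 25 higher in the interaction and 15 adjusted over the list alone (median 1; camera adjusted p = 7.19e-06, and adjusted p = 0.405 with an estimated correlation). Of 29 cell cycle genes, 25 were negative and 26 adjusted over the list alone (median -1.54; camera adjusted p = 1.43e-19, and adjusted p = 0.173 with an estimated correlation). All 11 neutrophil genes were positive, also adjusted over the list alone (median 3.11; camera adjusted p = 3.25e-11, and adjusted p = 0.0333 with an estimated correlation), the only list among those fixed beforehand called with an estimated correlation. Macrophages, inflammatory mediators, interferon response and erythroid lists were higher, with 7 of 15, 6 of 17, 5 of 11 and 4 of 8 genes positive and none, 1, none and none negative. Their camera adjusted p were 7.29e-05, 0.00102, 0.00444 and 0.00811, and adjusted p = 0.365, 0.365, 0.365 and 0.405 with an estimated correlation. Adjusted over the list alone, 9, 10, 5 and 5 were positive and 2, 1, 0 and 0 negative. Hedgehog and lymphocyte lists were lower, with 6 of 15 and 5 of 15 genes negative and 1 and 0 positive, and 7 and 5 negative adjusted over the list alone (camera adjusted p = 0.00444 and 0.00132, and adjusted p = 0.427 and 0.0748 with an estimated correlation). With dim genes left out the hedgehog, lymphocyte and erythroid lists were not called (0.0563, 0.0563 and 0.166). Endothelial genes and fibrillar collagens were not called as lists (adjusted p = 0.484 and 0.405). Of 14 endothelial genes 5 were positive and 2 negative, and 6 and 4 adjusted over the list alone, and of 12 collagens 2 and 3, and 2 and 4. Immediate early genes were called without B39 (0.0475). In all, 1792 genes had a positive and 2087 a negative interaction.

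**Figure D2:**
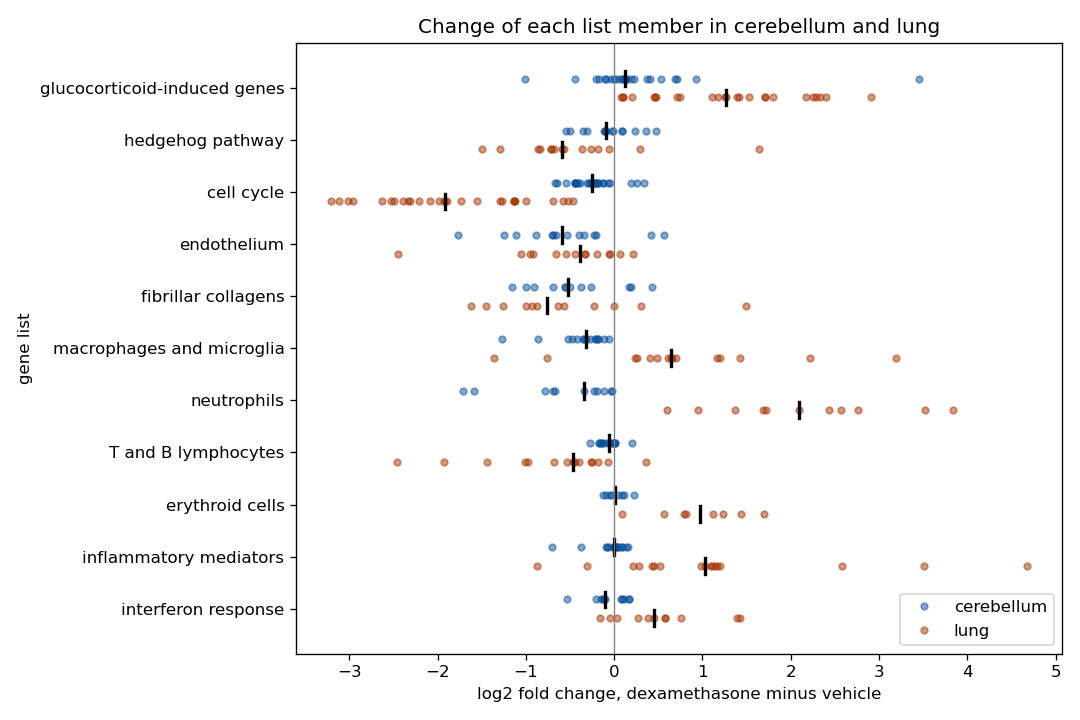
Log2 change after dexamethasone (horizontal axis) of each measured member of 11 lists (vertical axis) in cerebellum and lung, with a point per gene and a black bar at the median of the list. Neutrophil genes lie right of 0 in lung, with a median of 2.09, and left of it in cerebellum, with -0.34.

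Genes called in both organs were set beside the number independent lists would share. Of genes lower in both there were 113 against 55.5, a ratio of 2.04 (Fisher's exact test across genes, which are not independent replicates, p = 1.41e-14, and 5.64e-14 adjusted over 4 tests). With the cerebellar genes ranked by limma's statistic, another split of the cerebellar arrays placed 127 of the 358 lowest among genes lower in lung. Genes higher in both numbered 91 against 81.1 (Fisher's exact p = 0.22, adjusted 0.293). Higher in cerebellum and lower in lung were 93 against 80, and the reverse 60 against 56.3. Across genes the log2 changes of the organs correlated at 0.081 (Spearman 0.0628). Among genes that rose in both, Fam107a rose 10.9-fold in cerebellum and 4.86-fold in lung (2.71-fold without B46), Mal 3.12-fold and 2.61-fold, the hexokinase Hk2 2.25-fold and 2.68-fold, Scrg1 2.22-fold and 1.96-fold, the AP-1 factor Fosl2 1.87-fold in each, and Cyp4v3 1.84-fold and 2.71-fold. Among genes that fell in both, Aplnr fell 3.40-fold and 5.47-fold, Mid1 9.24-fold and 3.36-fold, the collagen Col1a1 2.23-fold and 3.08-fold, Mir1931 1.99-fold and 2-fold, the peptidase Prcp 1.91-fold and 2.67-fold, and Ripply3 2.09-fold and 1.90-fold. The cerebellar calls were lost for Hk2 without any array but B39 (adjusted p 0.0681 to 0.104) and for Fosl2 without any but B49 and B81 (0.0684 to 0.116). On the cerebellar arrays alone both were lost (0.0616 and 0.0799), and Hk2 also with Xist as a covariate (0.0598). With probe sets averaged Fosl2 had a log2 change of 0.45 in place of 0.91 (adjusted p = 0.157). In cerebellum 1 of 2 probe sets was called for Fosl2 and for Cyp4v3, and 2 of 4 for Prcp. The cerebellar calls were also lost for Mir1931 without B49, B50, B78 or B81 (0.0513 to 0.0712), and for Mal without B50, B79 or B80 (0.0535 to 0.0625). The lung call for Mid1 was lost without B31, B40, B14 or B22 (0.0551 to 0.0636), and its log2 change in cerebellum was -3.82 without B80. The number lower in both was 67 to 69 without B49, B50 or B79 and 174 without B46, and the number higher in both 51 to 59 without B50, B79 or B80.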

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

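The tests of B39, B46, brainstem markers and progenitors, the erythroid covariate, the splits for the overlap and the exact permutation tests were chosen after the data were seen; the other splits of the arrays were set before. Of 172 sets of 4 arrays looked at, 13 (7.56%) held an array far from the other 3, where chance gives about 1 in 20. Of these, B46 of the dexamethasone lungs accounted for 6: Tsc22d3 at 11.67, Hsd11b2 at 6.85, Mycn at 6.63, and the mean levels of the hedgehog list at 8.84, the fibrillar collagens at 10.90 and the endothelial list at 10.06. In the same group B31 stood apart in the neutrophil list at 10.06, and B40 in fatty acid synthesis at 10.17. Among vehicle lungs B19 stood apart for Ptch1 at 11.95 and B12 for the clock list at 7.83. In cerebellum these were the 18S control of B52 at 5.85, the microglial list of B79 at 7.73 and the sex-linked list of B81 at 6.04.

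The response differed between the organs for 3879 genes by the interaction test. Lists that differed had median interactions of 1 for glucocorticoid-induced genes, -0.61 for hedgehog, -1.54 for cell cycle, 0.88 for macrophages, 3.11 for neutrophils, -0.41 for lymphocytes, 0.94 for erythroid cells, 1.01 for inflammatory mediators and 0.42 for interferon response. With an estimated correlation only neutrophils among these 9 were called (adjusted p = 0.0333), and the others had adjusted p from 0.0748 to 0.427. Of 54 named genes, 32 differed. Negative values were -1.93 for Mybpc1, -1.51 for Ptchd4, -1.44 for Itih3, -1.68 for Gabra2, -0.61 for Ptch1, -1.27 for Mki67, -3.63 for Cenpf, -3.70 for Dcx, -3.36 for H2-Aa, -2.95 for Mdk, -3.46 for Cep55, -2.85 for Prss35, -3.36 for Plcxd3, -3.65 for Aspm and -0.48 for Prcp. Positive values were 1.19 for Scube2, 2.18 for Txnip, 1.48 for 8430419K02Rik, 1.45 for Clec14a, 2.69 for Cd68, 0.80 for Tek, 2.34 for Fkbp5, 1.20 for Per1, 4.68 for Cxcl2, 4.53 for Chil3, 3.60 for Serpina3n, 4.25 for Bpifa1, 4.29 for Inmt, 3.63 for Ms4a4d, 3.87 for Mmp8, 3.83 for Cd177 and 0.54 for Eln. The cerebellar means of Cxcl2, Chil3, Bpifa1, Ms4a4d, Mmp8 and Cd177 were at most 4.559 in either group, near the floor. Their interaction values are thus little more than the lung change. H2-Aa was also low in cerebellum, with means of 5.359 in vehicle and 4.982 in treated mice, so a fall there is hard to see. Without B46 the values of Serpina3n and Cxcl2 were 2.80 and 3.81, and without B31 that of Cxcl2 was 5.77. The interaction was lost for Scube2 without any array but B14 and B46 (adjusted p 0.0533 to 0.0928), and for Per1 without any but B19, B22, B31 and B80 (0.052 to 0.0941). Both were lost with the level of Xist as a covariate (0.0574 and 0.055), and Scube2 with a variance trend (0.0525). It was lost for Prcp without B14, B19, B22, B28, B40, B49, B52, B78 or B81 (0.0585 to 0.0806) or after quantile normalization (0.116), and for Eln with its probe sets averaged (0.0597). Genes not among the 32 also passed: Fam107a without B46 (-2.02, adjusted p = 0.00193), Chac1 without B39 (-1.14), Mid1 without B80 (2.07), Mobp without B78 (-1.71) or with probe sets averaged (-1.22), Gli1 without B81 (-0.83), Sftpb without B81 (0.86), Ccnd1 without B31 (-0.56) or averaged (-0.54), and Cyp4v3 averaged (0.95). Outside the genes tested, 152 probe sets without a single gene were called in cerebellum and 1668 in lung.

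The real split of the arrays was set against others of the same sizes. In cerebellum 1 of 35 splits, the real one, called 874 genes and the highest other 103. In lung 1 of 35 called 5679 and the highest other 39, and between tissues 1 of 35 called 10497 and the highest other 0. Of 100 draws of the labels within each tissue, 1, the real one, gave 3879 genes with an interaction and the highest other 2871. Another 3 draws split the lung arrays as the groups do and gave 2566 to 2871, and the remaining draws at most 17, so most of the count follows the split of the lung arrays. Chance is excluded at a share under 0.05 for the counts in cerebellum, in lung and between tissues, but litter or order of collection is not. For the interaction that share holds only against labels shuffled in both organs. With the lung split kept, 3 other draws are too few to exclude chance. For the overlap, the calls in lung were kept, and the 358 lowest and 516 highest genes of each split of the cerebellar arrays were taken by limma's statistic. Of 35 splits, each with the larger of its 2 directions, 2 gave at least the real 113 genes lower in both, with 127 as the highest other. For genes higher in both, 16 of 35 gave at least the real 91, with 113 as the highest other. Counted by direction, 2 of 70 assignments (a share of 0.0286) were as large for lower and 17 of 70 (0.243) for higher. The share of assignments for lower is under 0.05 and the share of splits, 0.0571, is not, so the verdict for genes lower in both depends on the counting. For genes higher in both chance is not excluded by either. It is not excluded for the number of lists in cerebellum either: 9 of 35 splits called at least as many as the real 8, and the highest other 11. In lung 1 of 35 called 17 lists, but the highest other called 16, so the preset correlation calls lists readily in these arrays.

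Oligodendrocyte and myelin genes were higher as a list in the treated cerebellum, with 4 of 18 called and an adjusted p of 0.489 with an estimated correlation, and tissue of the brainstem in the dissections is a candidate source. The brainstem markers, chosen after the data were seen, averaged 5.71 ± 0.69 in treated and 5.69 ± 0.55 in vehicle cerebella. They gave no sign of more brainstem in the treated group, but their spread is wide. With means this close, the marker level as a covariate could hardly move the list's median. The 98.8% left with it therefore decides nothing further. Without B39, the array highest in the markers, 83.5% was left, which argues against that array as the whole source. Without the vehicle array B79, the lowest in them at 4.895, the median was 0.21 against 0.36. An exact permutation test of the list's mean level gave p = 0.0857 (adjusted 0.257), so chance stays open, as do faster maturation and litter, which were untested.

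Neutrophil genes were higher as a list in the treated lung, 11 of 11 called, and lower in the treated cerebellum, 2 of 11, with adjusted p of 0.0544 and 0.405 with an estimated correlation. Without B46, which had the highest Cxcl2, 114% of the lung median was left, and with the erythroid level as a covariate 87.6%. This argues against B46 as the whole source, and against more blood of unchanged make-up only as far as the erythroid list measures it. The erythroid level itself differed with treatment by 0.968 on the log2 scale, so the covariate cannot fully separate blood from treatment. Blood richer in neutrophils was not tested. Of 15 lymphocyte genes 7 fell in the same lungs and 8 were not called. The list had a median log2 change of -0.46 and a camera adjusted p of 0.0544 with an estimated correlation. An exact permutation test of the neutrophil level gave p = 0.0286 in each organ, the smallest 4 against 4 arrays can give (adjusted 0.0381 in lung and 0.11 in cerebellum). A drug effect on neutrophil release or clearance, and infection of the treated lungs, may each account for it and were untested.

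Cell cycle genes lay lower as a list in the treated cerebellum with 0 of 29 called and an adjusted p of 0.607 with an estimated correlation. Without B39 49% of the median was left, so much of the shift may rest on this array, although camera still called the list (adjusted p = 0.0392). An exact permutation test of the list's mean level gave p = 0.257 (adjusted 0.386). A smaller share of granule neuron progenitors cannot be told apart from no change in them: that list had a median of -0.0272 and its mean an SE of 0.18, too wide to decide. No decrease in proliferation is shown, nor is it excluded.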

How the results depend on the processing

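Covariates for brainstem and erythroid markers, the leaving out of arrays for the overlap, and the alternatives for genes named by size of change, from lists, for the interaction or as shared were chosen after the data were seen. No call turned its direction in these alternatives. Counts of genes stayed within 1.5 times, apart from these. With every probe set on its own, probe sets called numbered 1456 in cerebellum, 10795 in lung, 6454 for the interaction, 21702 between tissues and 202 lower in both, since more features were tested. Array weights gave 1699 genes in cerebellum, 233 lower in both and 168 higher in both, and the brainstem covariate 1437 in cerebellum; the cause was not tested. Leaving out an array gave 528 to 847 genes in cerebellum, 67 to 174 lower in both and 51 to 126 higher in both. These fits have fewer samples, yet the highest counts in both lie above the 113 and 91 of the main fit. The cause was not tested. With an estimated correlation, lists called dropped from 8 to 0 in cerebellum, from 17 to 0 in lung and from 9 to 1 for the interaction. Only that setting of camera was changed, but the size of the correlation alone does not account for the drop. For the insulin-like growth factor list in cerebellum the estimate was -0.000395, below the preset 0.01. Its unadjusted camera p still rose from 0.00496 to 0.0113. The estimate was 0.603 for cell cycle and 0.514 for glucocorticoid-induced genes, against the preset 0.01. It was only 0.0287 for lymphocytes, which also lost their call. Adjusted p with an estimated correlation was 0.607 for cell cycle, 0.489 for oligodendrocytes and 0.102 for endothelium in cerebellum. In lung it was 0.208 for glucocorticoid-induced genes and for endothelium, 0.227 for hedgehog, 0.0801 for cell cycle, 0.142 for alveolar type 2 cells and 0.0544 for neutrophils, and for the interaction 0.405 and 0.173 for glucocorticoid-induced and cell cycle genes. The glucocorticoid-induced list in cerebellum ranged from an adjusted p of 0.0114 to 0.264 over arrays left out. For the interaction, the fit on only the arrays compared uses the same 16 arrays and gave no further value. No paired analysis was possible because the groups share no replicate numbers. Signal over background is not known for single probe sets, so absence of a transcript could not be called.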

Other observations

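The tests in this part and their lists, apart from the clock, insulin-like growth factor and endothelial lists, were chosen after the data were seen. Genes of class II antigen presentation fell in the treated lung, 8 of 8, with a median log2 change of -1.88 (camera adjusted over the added lists, p = 1.88e-08, and adjusted p = 0.0016 with an estimated correlation). H2-Eb1 fell 10.4-fold, H2-Ab1 10.1-fold and the invariant chain Cd74 4.92-fold. In cerebellum 0 of 8 were called (adjusted p = 0.512), and the interaction list was called (adjusted p = 1.78e-07). The class II genes H2-Aa and H2-Ab1 had low vehicle means there, 5.359 and 5.828, against 12.116 and 10.105 in lung. A fall in cerebellum could thus hardly be seen for them, and their interaction is mostly the lung change. The clock genes of the lung moved both ways, with Nr1d1 up 4.82-fold, Bhlhe40 1.90-fold and Hlf down 2.99-fold, and camera did not call the list (adjusted p = 0.228), although its mean level did not overlap between the groups (exact permutation p = 0.0286, adjusted 0.0381). Binding proteins of insulin-like growth factor also went both ways there, with Igfbp6 up 6.58-fold and Igfbp2 down 8.09-fold (list adjusted p = 0.192).

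Genes that fell in both organs included members of the vessel wall. Of the 113 shared genes, 4 belong to the endothelial list fixed before the data were examined, of which 7 of 14 fell in cerebellum and 6 of 14 in lung. They are Aplnr, Cdh5, Tek and Tie1. Of the 14, 5 had a positive and 2 a negative interaction, Cdh5 and Tek among the positive. With the pericyte and basement membrane lists, added later, there are 13: also Notch3, Pdgfrb, Rgs5, Vtn, Lama2, Lama4, Lamb1, Nid1 and Nid2. The pericyte list fell in cerebellum (6 of 11, adjusted p = 6.16e-08) and in lung (7 of 11 with 1 higher, adjusted p = 2.73e-05), and so did basement membrane (7 of 14, adjusted p = 4.84e-11, and 8 of 14, adjusted p = 2.00e-05). With an estimated correlation the adjusted p was 0.00416 and 0.0123 in cerebellum and 0.011 and 0.061 in lung. The lists added after the data were seen are no independent evidence, Flt1 of the endothelial list rose 1.48-fold in cerebellum, and Notch3 was not called there with its probe sets averaged (adjusted p = 0.089). A smaller share of vessel-wall cells was tested as an explanation, but the outcome followed from the calls in each organ, so the test decides nothing.

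Chac1, Cebpg, Mthfd2 and Cth, targets of the amino acid stress response, rose in cerebellum 3.08-fold, 2.43-fold, 2.11-fold and 1.49-fold. Of the list of 20, added later, these 4 were called and 6 rose adjusted over the list alone, with a median log2 change of 0.11 (camera adjusted p = 0.00511, and adjusted p = 0.344 with an estimated correlation). A rise of the whole response was tested on the other members, but leaving out the called ones fixes the outcome, so the test decides nothing. In lung 10 of the 20 rose and 3 fell, 12 and 3 adjusted over the list alone (camera adjusted p = 0.00353, and adjusted p = 0.213 with an estimated correlation). The interaction of the list was not called (adjusted p = 0.419). The brainstem list, also added, had 0 of 19 genes called in cerebellum (adjusted p = 0.815).

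The fall of Mid1 rests on a single one of its 3 probe sets in both organs, with log2 changes of -3.21 in cerebellum (-3.82 without B80) and -1.75 in lung, where the call was lost without B31, B40, B14 or B22 (adjusted p 0.0551 to 0.0636). The others had mean levels of 4.483 and 4.679, against 7.508, too near the floor to show a fall well. The level of the probe set that fell varied within vehicle cerebella by 1.28 (SD, n = 4), against 0.64 in treated ones. No explanation was tested.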
